A study of Homo sapiens with 5 samples.

How the data were processed

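RNA from 5 human prostate cancer cell cultures was measured on 5 Illumina bead arrays, 1 array per culture, each array holding 47306 probes. LNCaP is an androgen-responsive prostate cancer line. LNRII is LNCaP carrying the TGF-beta type II receptor TGFBR2 from a lentivirus, selected with puromycin, per the labels' protocols. The LNRII cultures were grown for 3 days with TGFB3 at 5 ng/ml or with vehicle. The LNCaP cultures had received a lentivirus with a control hairpin (shCtr) or a hairpin against FOXA1 (shFOXA1) and are labelled day 10. A further shFOXA1 culture was given LY2157299 (galunisertib, an inhibitor of the TGF-beta type I receptor kinase) at 10 µM for 3 days. Whether the other 2 LNCaP cultures received vehicle over the same days is not given for each array.

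The deposited scanner table gives the mean bead intensity of each probe on each array, not normalized between arrays per the file headers, and its values show that no background had been subtracted. The same table gives a detection p-value per probe and array, which compares the probe with the negative controls of its array, per the file headers. The arrays were read out with GenomeStudio, per the submitters' processing notes, with no version given. A further table holds the authors' processed intensity values of the same arrays. How it was made is not given in the sources used here. Its values ranked the probes of each array as the scanner table did (Spearman's rho 1.00), 25.3% of them were negative, and the sorted values of arrays of the same line differed by a median of 0 while their maxima differed between the lines, so it was read as background-subtracted, linear and quantile normalized separately for each line. The medians of its columns were 4.7 on both LNRII arrays and 4.5 on the 3 LNCaP arrays. Its exact background method remains unknown.

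Of the 47306 probes, 30107 have 1 gene symbol in the platform table, 8 have several and 17191 are unnamed there. Entrez identifiers of 30068 probes were found in a human gene table of the assembly GRCh38.p14, and 0 symbols had to be updated. The named probes cover 20044 genes. No genome build is named for the array, so no coordinates are given.

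The main values were computed with limma 3.58.1 in R 4.3.3 by its neqc function: normexp background correction with the negative control level inferred from the detection p-values, an offset of 16, quantile normalization over all 5 arrays and log2. A probe was called detected on an array at a detection p below 0.01. Each gene was represented by the probe with the highest mean over the 5 arrays among its probes detected on at least 1 array, which gave 11808 genes. A gene entered a comparison if detected on at least 1 of its 2 arrays. Where a probe was not detected on the dim side, that side was raised to the lowest log2 value among the detected probes of that array, unless the probe's own value was higher, and the difference is then a lower bound, written "at least". Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

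There was 1 array per group, so no test, p-value or standard error for a difference between conditions can be given, and none of the differences has a replicate check. Genes are called higher or lower by a rule of size, at least 2-fold. The only error these arrays offer is the disagreement between probes of the same gene, which covers the measurement and not the spread between cultures. From genes with 2 detected probes, the SD of a log2 difference read by 1 probe was 0.22 for TGFB3 against control, 0.17 for shFOXA1 against shCtr, 0.15 for LY2157299 against shFOXA1 and 0.18 for LY2157299 against shCtr. The detection floor was log2 5.03 on the LNRII control array and between 4.67 and 4.72 on the other 4 arrays, and the signal above background sets how small a level can be compared.

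Before the data were examined, 4 comparisons, 33 gene lists, the named genes and 11 processing alternatives were fixed. The named genes of the comparisons of TGFB3 with control, shFOXA1 with shCtr and LY2157299 with shFOXA1 are the 12 with the largest increase and the 12 with the largest decrease, up to 4 detected members of each list with the largest absolute difference, and a fixed set of genes where measured, among them FOXA1, TGFBR1, TGFBR2, TGFBR3, TGFB1, TGFB2, TGFB3, SMAD7, KLK3, CDH1 and VIM. Genes without a named probe in the platform table are not analysed here. For genes shared by a pair of comparisons, the 10 with the largest smaller difference are named. The median of a list is placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. The random range named below holds the middle of these random medians. Of 33 lists with TGFB3, 11 lay above it and 5 below. After knockdown it was 9 and 4 of 33. With LY2157299 it was 4 and 9 of 33 against shFOXA1, and 10 and 6 of 32 against shCtr. By chance 1.65 of 33 or 1.6 of 32 would lie outside. Lying outside was thus common, and random lists do not copy how genes of a list move together. It does not by itself set a list apart.

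The shFOXA1 array serves in 2 comparisons with opposite sign and the shCtr array in 2 with the same sign, so array noise alone links them. Noise was simulated 100 times with an SD set by expression level in 5 bins, from the same pairs of probes, once without any effect and once with the measured knockdown differences and no effect of LY2157299. These simulations hold no spread between cultures and apply no detection floor. The simulation with knockdown differences adds noise to values that already hold noise. The comparison of TGFB3 with control shares no array with the others.

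The procedure was tested on simulated data: arrays imitating shFOXA1 against shCtr, with known changes in some of the 11584 genes compared. At a true fold of 3, 43 of 50 changed genes (86.0%) passed the 2-fold rule, and at 4, 41 of 50 (82.0%). Among changed genes in the brighter part of the range all 27 and all 17 passed at these folds, against 69.6% and 72.7% of dim genes, whose folds are compressed by the background and the floor. At a true fold of 2, 34.7% of 49 genes passed, and at 1.5, 0 of 50. Among 11385 unchanged genes 1 passed. The simulated arrays were all built from the shCtr profile with measurement noise and no spread between cultures. This count is therefore not the rate of false calls between real single cultures. The alternatives were no background correction, median centring, the authors' processed values, an offset of 50, a detection p below 0.05, detection on both arrays, no filter or floor, the mean over probes, separate normalization of the lines, and rules of 1.5-fold and 3-fold.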

Results

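The study measured mRNA in LNCaP prostate cancer cells and in LNRII, a derivative with added TGFBR2, a receptor of the growth factor TGF-beta. Its title asks about repression of TGF-beta signalling by FOXA1, a pioneer transcription factor of luminal prostate cells. There were 5 arrays and 5 conditions: LNRII with vehicle, LNRII with TGFB3, LNCaP with a control hairpin, LNCaP with a hairpin against FOXA1, and the latter with the receptor kinase inhibitor LY2157299. Between 32.3% (LNRII control) and 38.1% (shFOXA1) of the 47306 probes were detected, and the mean intensity lay between 278 and 310. The number of arrays limits the precision, as no condition was replicated. In what follows, higher and lower refer to the array values, genes counted as higher or lower differed by at least 2-fold, and signed values are log2 differences.

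FOXA1 itself was bright on every array. Its log2 intensity was 11.82 with the control hairpin, 11.26 with the FOXA1 hairpin and 11.30 with the hairpin and LY2157299, so the knockdown array held 67.8% of the control signal. The difference of -0.56 was several times the probe SD of 0.17 and short of 2-fold. In LNRII the FOXA1 values were 11.81 without and 11.92 with TGFB3. No named TGFBR2 probe was detected on either LNRII array. Whether they lie in the part of the transcript carried by the virus is not known here, so they check nothing about the receptor. In LNCaP no TGFBR2 probe was detected with the control hairpin. Those detected with the FOXA1 hairpin read 4.89 and 4.76, and 4.72 and 5.01 with LY2157299 added. These values lie near the detection floor, and a further TGFBR2 probe was not detected on any array. TGFBR1, TGFB1 and TGFB2 were not detected on any array.

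The comparison of LNRII cells with and without ligand addresses the response to TGF-beta in this line, with 1 culture on each side. TGFB3 in LNRII cells was accompanied by higher mRNA of androgen-metabolising reductases, matrix genes and known TGF-beta target genes. Lower were the mRNAs of glucuronidating enzymes of the UGT2B family and of cell cycle genes. Of 10711 genes measured, 200 were higher and 124 lower. The largest increase was that of AKR1C3, a reductase that makes testosterone from androstenedione, at 13.8-fold from a level at the detection floor of the control array (log2 5.03), with its relatives AKR1C4 (8.12-fold) and AKR1C2 (6.56-fold). The largest decreases were those of UGT2B genes, whose enzymes attach glucuronic acid to substrates that include androgens. UGT2B17 was 22.5-fold lower, UGT2B15 15.7-fold, UGT2B10 15.6-fold, UGT2B11 12.4-fold and UGT2B28 10.9-fold. On the LNCaP control hairpin array each of them read nearer to LNRII with TGFB3 than to the LNRII control. For UGT2B17 the log2 values were 7.90, 6.18 and 10.67, in that order. For these genes a LNRII control culture standing apart cannot be told apart from an effect of TGFB3.

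Other strongly higher genes were SGK1, a serum- and glucocorticoid-regulated kinase (3.29), the matrix protease MMP7 (3.04), coagulation factor F5 (2.91), FAM110B (at least 2.86), SLC22A23 (2.84), the matrix protein MATN2 (at least 2.79), TCIM (2.77) and PTGER4, a prostaglandin E2 receptor (2.67). SERPINA3, which encodes antichymotrypsin, was at least 7.42-fold higher. On the lower side stood RPRML (-2.46), the cadherin CDH26 (-2.33), the hydroxylase ASPH (-2.07), the semaphorin SEMA3D (-2.01 or lower), the tetraspanin TSPAN8 (-2.01), CHPT1, an enzyme of phosphatidylcholine synthesis (-1.96), and FAM72B (-1.95).

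Among 37 measured TGF-beta target genes, 9 were higher, 0 lower and 28 neither. They included PMEPA1, a feedback inhibitor of the pathway (2.57), the cell cycle inhibitor CDKN2B (at least 2.47), the matrix protein TGFBI (at least 2.18) and the transcription factor SNAI2 (at least 1.77). The list median was 0.29, above all 10000 matched random lists. In this comparison 11 of 33 lists had a median above the random range. Of 31 extracellular matrix genes 5 were higher and 0 lower, with a median of 0.39, also above all random lists; MMP10 (at least 2.13) and LAMB3 (at least 1.98) were among them. Pathway components SMAD3 (1.85), SMAD6 (1.63) and BAMBI (1.22) were higher, and the inhibitor SMAD7 stood at 0.25 on its brighter probe, while its second probe was not detected without TGFB3 and read 5.63 with it. The epithelial cadherin CDH1 stood at 0.45. Vimentin (VIM) stood at 0.01 on its brighter probe, and its second probe read 5.55 without and 5.97 with TGFB3.

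Proliferation genes moved the other way as a group. All 57 measured genes of G2 phase and mitosis lay below 0 and 16 were lower, among them the kinase PBK (-1.63), the kinetochore genes NUF2 (-1.18) and SPC25 (-1.14), and PTTG1, the securin (-1.13). Their median was -0.88. Of 50 genes of G1/S and DNA replication 47 lay below 0 and 3 were lower, TK1 (-1.21), CDC45 (-1.10) and RRM2 (-1.04), with a median of -0.50. Both medians were below all random lists. Of 35 androgen receptor targets 11 were higher and 3 lower, and the median was 0.46. The 3 lower genes were UGT2B15, UGT2B17 and UGT2B28, of which UGT2B15 and UGT2B17 also stand in the list of androgen-repressed genes. That list had 4 of 14 members lower, 3 higher and a median of -0.33, below the random range. KLK3, which encodes prostate-specific antigen, stood at 0.83. Ribosomal protein genes had a median of -0.02.

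Among genes with 2 probes detected on both arrays, 42 were 2-fold higher on the brighter probe. Of these, 35 were at least 1.5-fold higher on the second. On the lower side 23 of 27 were at least 1.5-fold lower on the second. Genes whose second probe was not detected on either or both arrays were not counted. AKR1C and UGT2B members have closely related sequences, so the values of single members are uncertain. Without background correction 77 genes were higher and 28 lower, and 23 of the higher and 18 of the lower genes rest on the detection floor of an array.

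FOXA1 knockdown in LNCaP cells was accompanied by higher mRNA of inflammatory genes, of actin and smooth muscle genes, and of TGF-beta target genes. It was also accompanied by lower mRNA of a family of TRIM genes and of the UGT2B enzymes UGT2B11, UGT2B28, UGT2B17 and UGT2B10. The reductases AKR1C2 (1.65) and AKR1C4 (1.62) were higher, while AKR1C3 stood at 0.62 and was short of 2-fold. Of 11132 genes measured, 124 were higher and 42 lower. RGS4, a regulator of G-protein signalling, was 11.8-fold higher, S100A9, a subunit of calprotectin, 8.85-fold, PI3, the elastase inhibitor elafin, 6.87-fold, the sphingosine-1-phosphate receptor S1PR3 6.38-fold and MYLK, the myosin light chain kinase, 6.37-fold. The 6 genes TRIM48, TRIM49C, TRIM49D1, TRIM49D2, TRIM51 and GRM5P1 were lower by nearly the same amount, between -2.48 and -2.14. The TRIM genes among them have related sequences. Sequences were not compared here, and how GRM5P1 relates to the others was not examined.

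Further higher genes were SGK1 (2.62), PIP (2.55), UGT1A1, an enzyme of bilirubin glucuronidation (2.48), TCIM (2.47), SERPINA3 (2.44), REPS2 (2.42) and the keratin pseudogene KRT16P2 (at least 2.39). Further lower genes were TARP, a prostate transcript of the T-cell receptor gamma locus (-2.09), relaxin RLN1 (-1.96), DDC, the aromatic amino acid decarboxylase (-1.91), HPGD, which degrades prostaglandins (-1.76), the imprinted gene PEG3 (-1.76) and UGT2B11 (-1.75).

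Of 16 inflammatory and NF-kB genes all lay above 0 and 5 were higher, including the chemokines CCL2 (2.19) and CXCL8 (1.77), lipocalin LCN2 (2.13) and serum amyloid SAA1 (1.76). Their median of 0.65 was above all 10000 random lists. Of 35 TGF-beta targets 33 lay above 0, 6 were higher and 0 lower, with SNAI2 (1.98), IGFBP3 (1.81), thrombospondin THBS1 (1.52) and smooth muscle actin ACTA2 (1.35) in front and a median of 0.37, above all random lists. PMEPA1 was an exception at -0.17. TGFB3 was not detected with the control hairpin and was at least 2.07-fold higher with the FOXA1 hairpin, and its co-receptor TGFBR3 was higher by 1.26. SMAD7 stood at 0.10 on its brighter probe, while its second probe read 5.53 with the control hairpin and 5.44 with the FOXA1 hairpin. The actin and smooth muscle list had 3 of 24 members higher, MYLK, ACTA2 and ACTG2 (1.73), and a median of 0.35.

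Cell cycle genes were lower as groups without a member reaching 2-fold. Of 56 mitotic genes 55 lay below 0 (median -0.41, SPC25 at -0.78), and of 51 replication genes 48 did (median -0.41, MCM2 at -0.76). Androgen receptor targets had a median of -0.15, with 3 of 35 higher and 4 lower. The transcription factor MAF (1.94) was the most increased of them, and HPGD, UGT2B28 (-1.69) and SLC45A3 (-1.67) the most decreased. KLK3 stood at 0.08. Of the 42 lower genes 2 and of the 124 higher genes 15 rest on a detection floor, and without background correction 41 genes were higher and 15 lower.

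**Figure D1:**
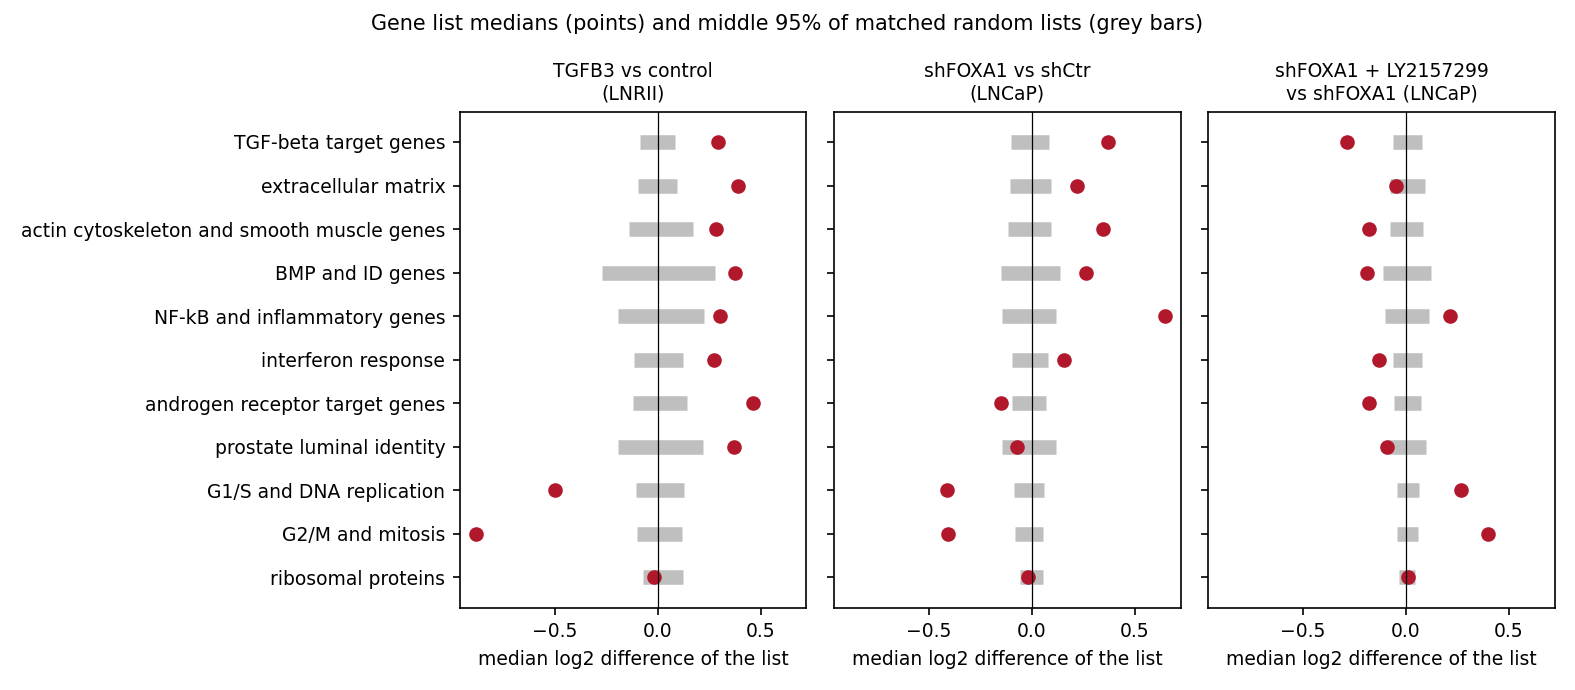
Median log2 difference (horizontal axis) of 11 fixed gene lists in 3 comparisons, each of 1 array against 1 array; points are list medians and grey bars hold the middle 95% of 10000 random lists matched on size and expression. TGF-beta targets lie at 0.29 with TGFB3, 0.37 with shFOXA1 and -0.29 with LY2157299, and mitotic genes at -0.88, -0.41 and 0.40.

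LY2157299 in the knockdown cells was accompanied by few differences of 2-fold, mostly decreases, and by small shifts of whole groups: the medians of TGF-beta targets, of the ATF4 and unfolded protein response, of glycolysis and hypoxia genes, of actin genes and of androgen receptor targets were below all 10000 random lists, and those of cell cycle genes above. Of 11002 genes measured, 6 were higher and 23 lower. The calcium-binding protein S100P was 5.07-fold lower, followed by the keratin-associated KRTAP13-2 (-1.67), CRYAB, a small heat shock protein (-1.63), KRT16P2 (-1.57), FAXDC2 (-1.56), FHL2, a LIM-domain cofactor (-1.56 or lower), the secreted glycoprotein AZGP1 (-1.54), DEFB132 (-1.41), TCIM (-1.37), AGR3 (-1.34), UGT1A1 (-1.27) and the chloride exchanger SLC26A3 (-1.24). The 6 higher genes were the chemokines CCL20 (1.41) and CXCL8 (1.04), ANGPT2, an angiopoietin (1.12), the small GTPase RAC3 (1.11), the kinase MAP2K6 (at least 1.08) and CAMTA1 (1.03).

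Of 36 TGF-beta targets none reached 2-fold, but 26 lay below 0, with ACTA2 at -0.86, CCN2 at -0.84, CDKN2B at -0.72 and PMEPA1 at -0.70. Above 0 lay 9, among them SNAI2 at 0.20 and VIM. The VIM probes read 6.94 and 4.84 with the control hairpin, 7.41 and 5.77 with the FOXA1 hairpin, and 7.95 and 6.40 with LY2157299 added. The list median of -0.29 was below all 10000 random lists. Of 24 actin and smooth muscle genes 21 lay below 0 (median -0.18) and 1, MYLK (-1.24), was lower. All 56 mitotic genes lay above 0, with BUB1, DLGAP5 and CDK1 each at 0.61 and a median of 0.40. Of 50 replication genes 45 lay above 0, with a median of 0.27. Inflammatory genes, already raised on the knockdown array, had a median of 0.22, with 2 of 16 higher, CCL20 and CXCL8, and LCN2 at 0.81. Androgen receptor targets had a median of -0.18 and 2 lower members, NDRG1 (-1.18) and the prostatic acid phosphatase ACP3 (-1.03). Of 3 genes 2-fold apart with 2 probes detected on both arrays, the 2 higher ones were at least 1.5-fold higher on the second probe. The lower gene was not lower on its second probe. Without background correction 1 gene was higher and 5 were lower.

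The cells with knockdown and LY2157299 still differed from the control hairpin cells, with 101 of 11019 genes higher and 57 lower. Inflammatory genes had a median of 0.85 (6 of 16 higher). TGF-beta targets had a median of 0.16, with 4 of 34 higher, mitotic genes a median of 0.01 and replication genes a median of -0.12, with 36 of 51 below 0. Androgen receptor targets had a median of -0.35, with 5 of 36 lower and 1 higher. PMEPA1 stood at -0.87 in this comparison. Extracellular matrix genes had a median of 0.30 in it and of 0.22 after knockdown alone, both above all 10000 random lists. With LY2157299 against shFOXA1 their median was -0.05, within the random range. Mesenchymal markers had a median of 0.30 with LY2157299 against shCtr, above the random range, and lay within that range in the other comparisons. Of the 124 genes higher after knockdown, 73 were still 2-fold above the control hairpin with LY2157299 and 51 (41.1%) were not, where simulated probe noise, which holds no spread between cultures, gave 18.0% (8.57% to 26.1% over 100 runs) without an effect of LY2157299. Their median was -0.24 with LY2157299 against shFOXA1, where the simulation gave -0.042. The simulation took the measured knockdown differences as true and added noise to them again. It gave on average 147 higher and 54 lower genes after knockdown, against 124 and 42 measured. It may therefore understate how far genes picked at 2-fold fall back without any effect of LY2157299. Of the 42 genes lower after knockdown, 34 were still 2-fold lower and 19.0% were not, within the 14.3% to 42.9% of the simulation (mean 26.5%). Their median with LY2157299 was -0.068 against 0.064 in the simulation, a value that changed sign when genes were picked at 1.5-fold (0.13). Without background correction 35 genes were higher and 15 lower than with the control hairpin.

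Genes that responded to TGFB3 in LNRII went the same way after FOXA1 knockdown in LNCaP, on arrays not used to pick them. The 194 TGFB3-higher genes measured there had a median of 0.37, 155 lay above 0 and 38 were higher, where 2.00 shared genes would be met by independent lists. The shared genes with the largest differences were SGK1, TCIM, SERPINA3, MAF, SNAI2, CRYAB, AKR1C2, AKR1C4, GBP2 and NDRG1. The 109 TGFB3-lower genes had a median of -0.39 and 9 were lower, against 0.396 for independent lists: UGT2B11, UGT2B28, UGT2B17, UGT2B10, DDC, PRUNE2, TRIM49D1, NUP93 and ANKRD37. The UGT2B genes have closely related sequences and moved together, as did AKR1C2 and AKR1C4 on the higher side. They are not separate readings, so the numbers for independent lists do not measure how unusual the sharing is. For the UGT2B genes a LNRII control culture standing apart also stays open. No gene was 2-fold apart in opposite directions. Across 10180 genes, which are not independent replicates, the differences of these comparisons correlated at Pearson's r = 0.410 and Spearman's rho = 0.375.

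With LY2157299 the TGFB3-higher genes had a median of -0.22, 141 of 191 lay below 0 and 9 were lower, against 0.396 for independent lists: CRYAB, AZGP1, TCIM, FHL2, FAXDC2, EMP1, NDRG1, AKR1C2 and OR51E2. The TGFB3-lower genes had a median of 0.25, which was 0.11 for the 90 genes outside the cell cycle lists, and CCL20, at -1.62 with TGFB3, was the 1 of them that was 2-fold higher. Every one of these medians lay outside the range of all 10000 random lists. Pearson's r across 10131 genes was -0.256 and Spearman's rho -0.218. Set against the control hairpin, the medians with knockdown and LY2157299 remained at 0.25 for TGFB3-higher and -0.13 for TGFB3-lower genes. SGK1 stood at 2.49 and SERPINA3 at 2.64 there, against 2.62 and 2.44 after knockdown alone, and CRYAB (0.61), NDRG1 (0.43) and AKR1C2 (0.50) were no longer 2-fold apart.

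**Figure D2:**
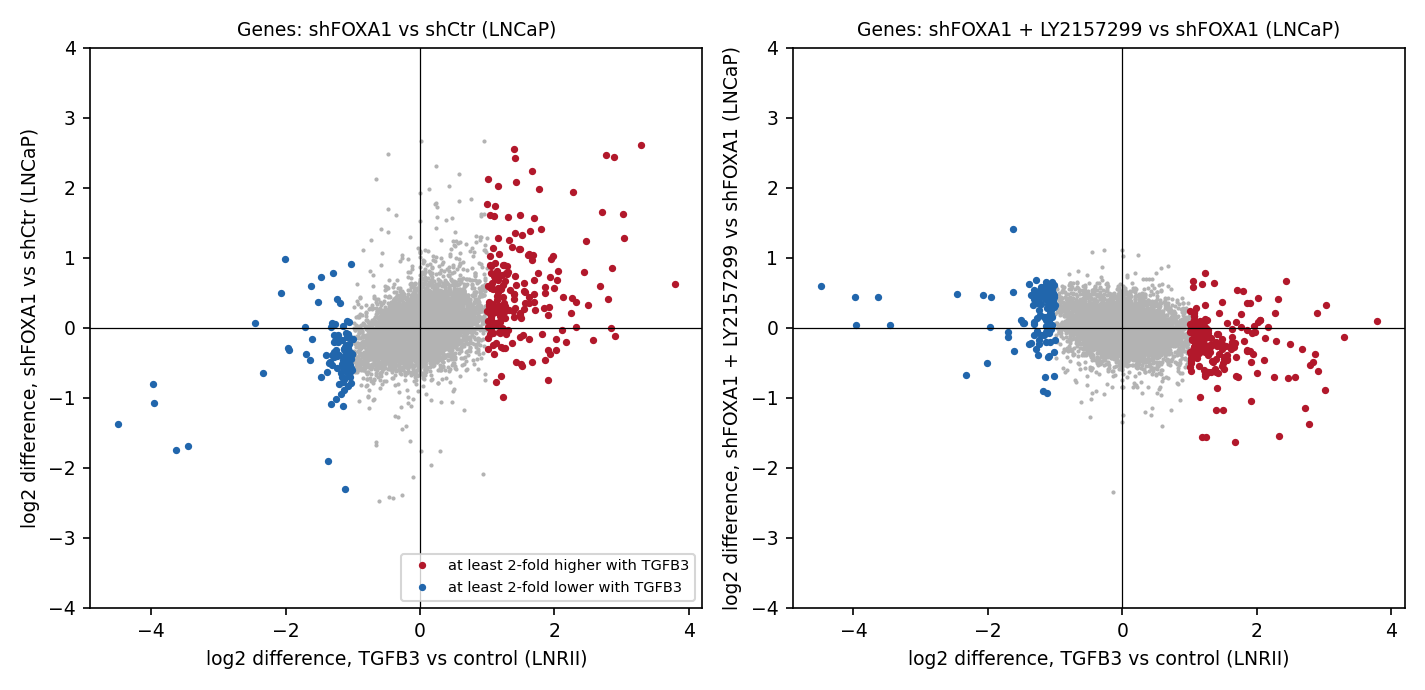
Log2 difference of each gene with TGFB3 in LNRII (horizontal axes) against its log2 difference after FOXA1 knockdown (left) and with LY2157299 in knockdown cells (right); red and blue points are genes at least 2-fold higher or lower with TGFB3 and grey points all others. The red points have a median of 0.37 on the left and -0.22 on the right, the blue points -0.39 and 0.25.

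The comparisons of knockdown and of LY2157299 share the shFOXA1 array. Across 10803 genes their differences correlated at r = -0.319, where simulated noise gave -0.500 without any effect and -0.234 with the knockdown effect alone. The covariance was -0.0229 against -0.0159 in both simulations, a difference of -0.0070. Of genes higher after knockdown, 12 were lower with LY2157299, among them CRYAB, KRT16P2, TCIM, AGR3, UGT1A1, SLC26A3 and MYLK, where independent lists would share 0.264, a number that takes no account of the shared array.

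**Figure D3:**
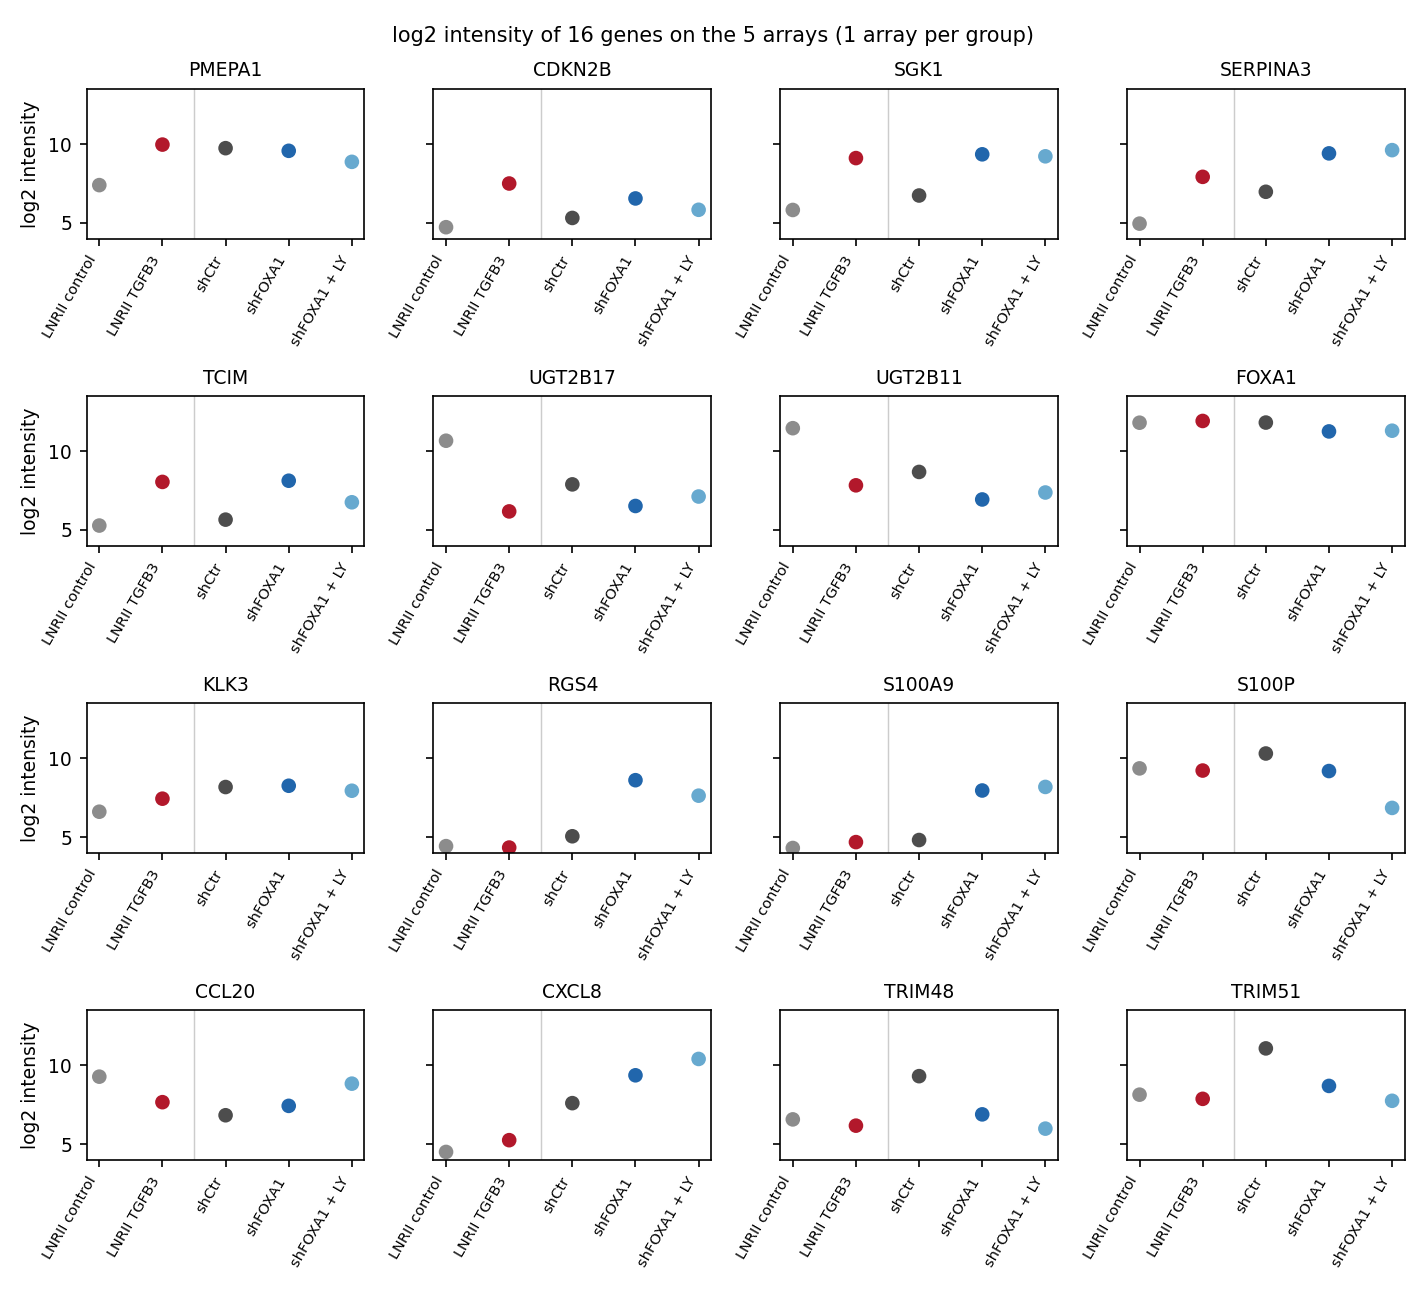
Log2 intensity (vertical axes) of 16 genes on each of the 5 arrays, 1 point per array, with LNRII left and LNCaP right of the grey line. SGK1 stands at 5.82 and 9.11 without and with TGFB3 and at 6.74 and 9.35 without and with FOXA1 knockdown, and FOXA1 itself lies between 11.26 and 11.92 on all arrays.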

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

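Probes without a single gene name in the platform table took no part in the comparisons above, and counting them was not planned before the data were examined. Among 3888 such probes measured with TGFB3 against control, 107 were at least 2-fold apart (2.75%, against 3.02% of named genes), 33 higher and 74 lower, where named genes had 200 higher and 124 lower. After FOXA1 knockdown it was 31 probes (0.706%, against 1.49% of named genes), 13 higher and 18 lower, where named genes had 124 higher and 42 lower, with LY2157299 against shFOXA1 6 probes, and with LY2157299 against shCtr 35 probes. Which transcripts they read was not analysed here.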

How the results depend on the processing

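The alternative without the cell cycle lists was chosen after seeing the data and the others before. Counts and group medians depended on how background and dim genes were handled, while no named gene that passed the 2-fold rule changed sign. Of 139 such differences of named genes, counted in each comparison where a gene passed, 83 still passed it without background correction, 109 with an offset of 50, 130 with the mean over probes, 135 on the authors' values, 138 with median centring and with separate normalization, and all 139 with a detection p below 0.05 and without filter and floor. With detection required on both arrays, 125 had a value and all 125 passed. Beyond the results below, of the values of single genes, other lists and rank correlations 4174 stayed within their spread, 658 moved beyond it and 1 reversed. Values are given below where a count changed by over 1.5 times or a value by over 1 SD, taken from random lists for medians, resampled genes for r and probe pairs for genes. Each comparison is named by what was added.

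Without background correction, the counts of higher and lower genes were 77 and 28 (TGFB3), 41 and 15 (knockdown), 1 and 5 (LY2157299) and 35 and 15 (LY2157299 against shCtr). Shared genes numbered 11 (higher with TGFB3 and knockdown), 4 (lower in both) and 2 (higher with TGFB3 and lower with LY2157299). TGFB3-higher genes had medians of 0.27 (knockdown), -0.18 (LY2157299) and 0.12 (LY2157299 against shCtr). TGFB3-lower genes had medians of -0.35 (knockdown) and -0.047 (LY2157299 against shCtr). Knockdown-lower genes had medians of -0.38 (LY2157299) and -1.87 (LY2157299 against shCtr). Pearson r was 0.437 (TGFB3 with knockdown), -0.287 (TGFB3 with LY2157299) and -0.289 (knockdown with LY2157299). The TGF-beta target median was 0.11 (TGFB3), 0.26 (knockdown), -0.13 (LY2157299) and 0.10 (LY2157299 against shCtr). With an offset of 50, the counts of higher and lower genes were 120 and 53 (TGFB3), 68 and 22 (knockdown), 2 and 12 (LY2157299) and 53 and 27 (LY2157299 against shCtr). Shared genes numbered 20 (higher with TGFB3 and knockdown) and 5 (higher with TGFB3 and lower with LY2157299). TGFB3-higher genes had medians of 0.34 (knockdown) and 0.18 (LY2157299 against shCtr). TGFB3-lower genes had a median of -0.36 (knockdown). Knockdown-lower genes had medians of -0.18 (LY2157299) and -1.76 (LY2157299 against shCtr). Pearson r was 0.428 (TGFB3 with knockdown) and -0.277 (TGFB3 with LY2157299). The TGF-beta target median was 0.20 (TGFB3), 0.32 (knockdown) and -0.21 (LY2157299). At 1.5-fold, the counts of higher and lower genes were 707 and 711 (TGFB3), 368 and 205 (knockdown), 70 and 136 (LY2157299) and 335 and 258 (LY2157299 against shCtr). Shared genes numbered 140 (higher with TGFB3 and knockdown), 75 (lower in both), 42 (higher with TGFB3 and lower with LY2157299) and 22 (the reverse). TGFB3-higher genes had medians of 0.24 (knockdown), -0.11 (LY2157299) and 0.15 (LY2157299 against shCtr). TGFB3-lower genes had medians of -0.27 (knockdown), 0.14 (LY2157299) and -0.10 (LY2157299 against shCtr). Knockdown-higher genes had medians of -0.20 (LY2157299) and 0.71 (LY2157299 against shCtr). Knockdown-lower genes had medians of 0.13 (LY2157299) and -0.61 (LY2157299 against shCtr). At 3-fold, the counts of higher and lower genes were 63 and 20 (TGFB3), 48 and 16 (knockdown), 0 and 3 (LY2157299) and 32 and 16 (LY2157299 against shCtr). With detection required on both arrays, shared genes numbered 5 (higher with TGFB3 and lower with LY2157299). TGFB3-lower genes had a median of 0.28 (LY2157299). Knockdown-lower genes had a median of -1.38 (LY2157299 against shCtr). The TGF-beta target median was 0.37 (TGFB3), 0.43 (knockdown) and -0.33 (LY2157299). With median centring, TGFB3-higher genes had medians of 0.44 (knockdown), -0.23 (LY2157299) and 0.28 (LY2157299 against shCtr). TGFB3-lower genes had a median of -0.36 (knockdown). Knockdown-higher genes had a median of -0.27 (LY2157299). Pearson r was 0.395 (TGFB3 with knockdown). The TGF-beta target median was 0.23 (TGFB3), 0.44 (knockdown) and 0.22 (LY2157299 against shCtr). On the authors' processed values, TGFB3-higher genes had a median of 0.40 (knockdown). Knockdown-higher genes had a median of 1.08 (LY2157299 against shCtr). Without filter and floor, TGFB3-higher genes had medians of 0.35 (knockdown), -0.18 (LY2157299) and 0.18 (LY2157299 against shCtr). TGFB3-lower genes had medians of -0.28 (knockdown), 0.092 (LY2157299) and -0.069 (LY2157299 against shCtr). Knockdown-higher genes had a median of -0.27 (LY2157299). Pearson r was 0.324 (TGFB3 with knockdown), -0.181 (TGFB3 with LY2157299) and -0.348 (knockdown with LY2157299). The TGF-beta target median was 0.25 (TGFB3), 0.22 (knockdown), -0.11 (LY2157299) and 0.068 (LY2157299 against shCtr). The BMP and ID list with TGFB3 turned from 0.38 to -0.065. With the mean over probes, TGFB3-higher genes had a median of 0.21 (LY2157299 against shCtr). TGFB3-lower genes had medians of 0.19 (LY2157299) and -0.17 (LY2157299 against shCtr). Knockdown-higher genes had a median of -0.26 (LY2157299). Knockdown-lower genes had a median of -1.35 (LY2157299 against shCtr). The TGF-beta target median was 0.43 (knockdown). With a detection p below 0.05, TGFB3-lower genes had a median of 0.20 (LY2157299). Knockdown-higher genes had a median of -0.26 (LY2157299). Pearson r was 0.396 (TGFB3 with knockdown). Without the cell cycle lists, TGFB3-lower genes had medians of 0.11 (LY2157299) and -0.22 (LY2157299 against shCtr).

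Leaving the background in, or adding an offset of 50, shrinks every fold of a dim gene by construction, and looser or stricter rules change the counts by construction. The cause was not tested for the other changes. The median of knockdown-lower genes with LY2157299 changed sign at 1.5-fold, so it has no settled direction. Without background correction 73.3% of the 2-fold genes with TGFB3 were higher, against 61.7%. Separate normalization of the lines left each of these results within its spread. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Signal over background limits what can be compared: the LNRII control array detected the fewest probes (15273).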

Other observations

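The tests on second probes and without the cell cycle genes were written before their results were seen, and all other tests described here were chosen after the results. With TGFB3, 23 of 30 glycolysis and hypoxia genes lay below 0 (median -0.21), with ANKRD37 (-1.25) and hexokinase HK2 (-1.11) lower and the stress-responsive NDRG1 (1.49) higher. After FOXA1 knockdown the same list had a median of 0.03, with NDRG1 (1.61) and ANKRD37 (-1.02) as the members 2-fold apart, and with LY2157299 24 of 30 lay below 0 (median -0.21, below all 10000 random lists). Genes of the ATF4 and unfolded protein response had medians of -0.15, -0.03 and -0.22 in these comparisons, the second turning to 0.021 with median centring. With LY2157299 34 of 37 lay below 0 and the median was below all random lists, led by the amino acid transporters SLC7A5 (-1.15) and SLC7A11 (-0.56), and with TGFB3 the folate enzyme MTHFD2 (-1.10) and STC2 (-1.01) were lower.

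Luminal identity genes had a median of 0.37 with TGFB3, with AGR2 (1.51) higher, and of -0.07 after knockdown, with TARP (-2.09) lower. Epithelial genes were not lower with TGFB3: 23 of 30 lay above 0, KRT19 was higher (1.26), and the median was 0.27. Interferon response genes had medians of 0.28 with TGFB3, 0.15 after knockdown and -0.13 with LY2157299, with ISG20 (1.38) higher with TGFB3 and CXCL10 (1.23) higher after knockdown. Neuronal and neuroendocrine genes had medians within the random range in the same comparisons (0.04, -0.03 with a mean of 0.016, and 0.12) and above it with LY2157299 against shCtr (0.19, 10 of 13 above 0), and TUBB3 (2.44) and NRP1 (1.76) were higher with TGFB3. In the Notch list HES6 (-1.29) was lower and JAG1 (1.27) and LFNG (1.07) higher with TGFB3. Of markers of other cell types, 1 of 15 fibroblast, 4 of 18 blood, 3 of 10 endothelial and 1 of 8 kidney packaging-cell genes on the array were detected on any array. Of 13 prostate basal genes on the array 6 were detected. Their median was 0.35 after knockdown and 0.37 with LY2157299 against shCtr, both above the random range. It was -0.19 with TGFB3 and -0.04 with LY2157299 against shFOXA1, both within that range.

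TGFB3-higher genes were higher after FOXA1 knockdown and lower with LY2157299, and TGFB3-lower genes the reverse. Error of the shFOXA1 array alone would leave no rise between the other LNCaP arrays, where the median of the TGFB3-higher genes was 0.25. That covers only the rise. The fall with LY2157299 (-0.22) was read against the shFOXA1 array, so error of that array stays open for the fall. Error of the shCtr array stays open for the rise, since the median without that array (-0.22) covers only the fall. Cross-hybridisation of the chosen probes is argued against only for genes with a second probe. After knockdown these were 66 TGFB3-higher genes (median 0.33), against 194 on the brighter probe. On second probes of TGFB3-lower genes the median was -0.25 after knockdown (35 genes, against 109 on the brighter probe) and 0.13 with LY2157299 (34 genes). Against shCtr it was -0.027 with LY2157299, within the random range. The other genes were not checked. The listed cell cycle genes were not the whole of the shift of TGFB3-lower genes with LY2157299. Outside those lists the median was 0.11, against 0.25 with them, so these lists carry much of that shift. Cell cycle genes missing from the lists stay among the remaining genes, so the test cannot exclude a wider cell cycle cause. Growth cannot be told apart from TGF-beta signalling, since replication genes were below the random range (-0.12) where the 0.25 was measured, although mitotic genes were at 0.01, and mitotic genes rose with LY2157299 (0.40). A TGF-beta response that follows FOXA1 loss stays open as a hypothesis beside differences between single cultures, and no test here decides between them.

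TRIM48, TRIM49C, TRIM49D1, TRIM49D2, TRIM51 and GRM5P1 were lower together after knockdown, and with LY2157299 their values lay between -1.06 and -0.68. The shCtr culture standing apart on its own cannot be told apart from an effect of the hairpin: the median level was 9.24 on shCtr, 6.88 on shFOXA1, and 6.74 and 6.28 on the LNRII arrays with FOXA1 intact, and the median of -0.94 between the knockdown arrays covers only the later fall. Whether the probes read 1 common transcript cannot be told apart from a joint change: the SD between the genes was 0.851 times that of a single probe with LY2157299 but 1.60 times with TGFB3. TRIM49, near background on every array, stood at -0.15 or lower after knockdown and was left out of the group after its value was seen; with it at that bound, the ratio after knockdown is 5.05 instead of 0.738. No biological explanation was tested.

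Inflammatory genes had a median of 0.65 after FOXA1 knockdown and rose further as a list with LY2157299 (0.22). An interferon response to virus or hairpin as the source of both rises is argued against by interferon genes, whose median was -0.13 with LY2157299, but it stays open for the first rise, where that median was 0.15. Whether LY2157299 acted at all in that culture cannot be decided from these arrays. TGF-beta targets stood at -0.29 on them, but that was read against the shFOXA1 array, where the targets had stood at 0.37 against shCtr. A shFOXA1 array or culture reading high would give such a fall without any action of the inhibitor. With TGFB3 in LNRII the same list had a median of 0.30, above the random range, with 11 of 15 genes above 0 and CCL20 at -1.62. Differences between single cultures stay open, and no biological explanation was tested.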
